A study of Homo sapiens with 23 samples.

How the data were processed

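Upstream steps are given per the submitters' processing notes: reads were trimmed to 50 bases with Trim Galore 0.65, aligned with STAR 2.7.0 to GRCh38 (hg38), and counted per gene with HTSeq-count against GENCODE v38. Libraries were made with ribosomal RNA depletion (TruSeq Stranded Total RNA) and sequenced paired-end on an Illumina NextSeq, per the labels' protocols. The unit of the deposited table is the count: it holds whole numbers per gene and library, per the labels a raw count. The notes also mention CPM and gene-length normalisation by the authors; the deposited values are not scaled, and CPM was computed here. The strand setting of HTSeq-count is not stated, and the identifier versions resemble a release older than the one stated.

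The table had 57521 genes. Of these, 44 pseudoautosomal copies on the Y chromosome had 0 counts and were left out, so 57477 were used. Symbols and positions came from GENCODE v44 for GRCh38, which holds 56387 of the identifiers and lacks 1090. All 23 libraries were kept, and no duplicated library was found. Total counts per library were lowest on average at days 5 to 14, where small changes in weakly expressed genes are least precise.

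Differential expression used edgeR 4.0.16 in R 4.3.3, with limma 3.58.1. Genes were kept by filterByExpr with a minimum of 10 counts, scaled by TMM, and fitted in 1 robust quasi-likelihood model of all 23 libraries with the day as factor. Each of 8 comparisons was tested with the quasi-likelihood F-test, with p-values adjusted by Benjamini-Hochberg and a gene called at adjusted p under 0.05, with no fold threshold. Moderation shares the spread across genes, as libraries per day are few. A total of 27 gene lists (513 members, 510 matched) was fixed before the data were examined, and tested with camera at a preset correlation of 0.01, adjusted over 216 tests. The same tests with an estimated correlation, and fry, served as alternatives. Counts "adjusted over the list alone" apply Benjamini-Hochberg to the members of that list only.

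The genes named follow a rule: the 10 largest rises and 10 largest falls among called genes with a characterised symbol, a mean of at least 20 CPM on the higher day and no overlap between libraries of the 2 days; members of the lists; the 3 lipin genes; NPPA and NPPB; and genes at LPIN1. Where the text could not hold all, the largest changes came first. Within lists, members with large changes whose call held without each library were preferred, a preference set after the values were seen. Genes named whose call did not hold are given with the value at which it ended. A gene with 0 counts on 1 day is given only as at least a fold, from a floor of 3 counts over that day, and "all-zero members at their bound" uses that floor. Genes with 1 to 3 counts on the lower day are given in CPM.

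Alternatives were RLE, upper-quartile and library-total scaling, mitochondrially encoded genes left out, DESeq2 1.42.0, other filters, the replicate number as a block, only the libraries of the 2 days, and each library left out in turn. Added later were a fit with GC content and gene length trends removed (both known for 21987 of the 22245 genes tested) and a fit without the 4 libraries with the highest scores on a within-day axis. In a simulated check on 21614 genes, the test found 7 of 100 genes changed 2-fold and 78 of 100 changed 4-fold for day 10 against day 7, and 27 and 91 for day 28 against day 14. It called 5 unchanged genes in each. A sarcomere list shifted 1.5-fold was called and 0 of 52 tests of lists not shifted were, by camera. Genes were simulated independently of one another, so this check could not show false calls of lists whose members vary together.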

Results

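Ribosomal RNA-depleted total RNA was sequenced from H1-hESC cells during directed differentiation into cardiomyocytes. H1-hESC is an established human embryonic stem cell line, and the labels give its genotype as wild type. Cells were collected at 8 times, from day 0 to day 28, with 3 libraries per day except day 10, which had 2. The labels name day 0 as stem cells, day 1 as mesendoderm, day 3 as cardiac mesoderm, days 5 and 7 as cardiac progenitors, and the last 3 days (10, then 14 and 28) as cardiomyocytes. Total counts assigned to genes ranged from 4330334 (day 5 replicate 3) to 22089595 (day 0 replicate 2), and 22245 genes were tested. Levels are given in CPM, counts scaled to the library size, as mean ± SD over 3 libraries, or over 2 at day 10. No other differentiation, cell line or undifferentiated control at later days was analysed here, so each day is compared with the day before it and day 28 also with day 0. The p-values measure only the spread between these libraries.

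The first principal component held 66.3% of the variance of the 2000 most variable genes and the second 15.4%. Pearson correlations between libraries of the same day, across genes, lay between 0.968 and 0.993 on every day but day 5, where they lay between 0.907 and 0.956. The mitochondrially encoded messenger RNAs took 1.22% of counts at day 0, 2.88% at day 14 and 1.91% at day 28. The replication-dependent histone genes took 0.963% at day 0, 2.18% at day 1 and 0.0813% at day 28.

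**Figure D1:**
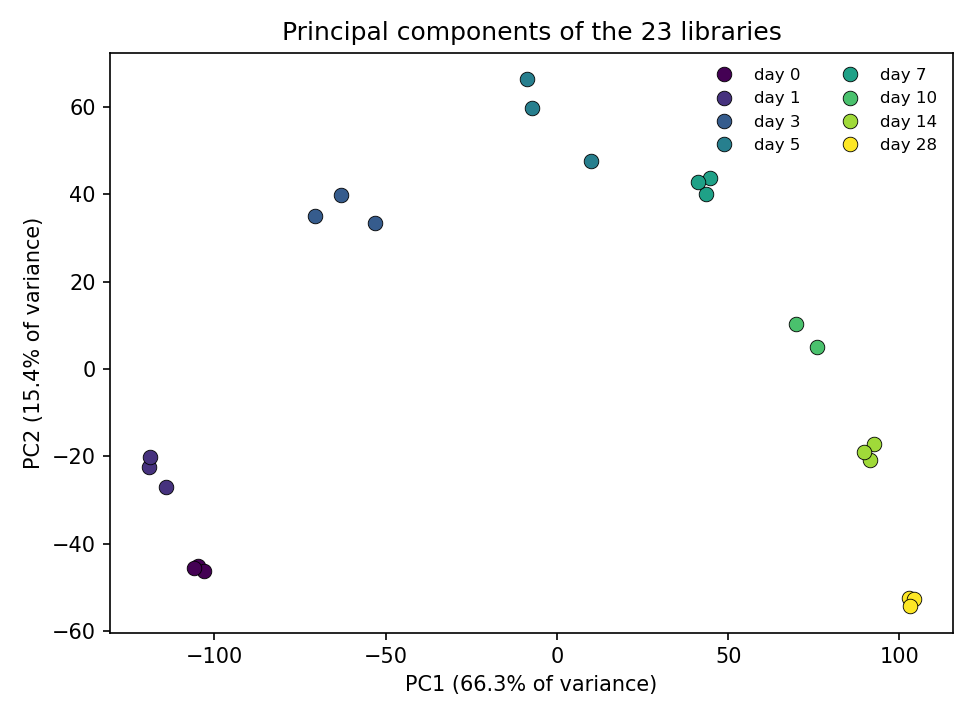
Each point is a library, placed by the first (66.3% of variance) and second (15.4%) principal components of log2 CPM over the 2000 most variable genes, and coloured by day. Libraries of the same day lie near one another, and the days follow one another along a curve.

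**Figure D2:**
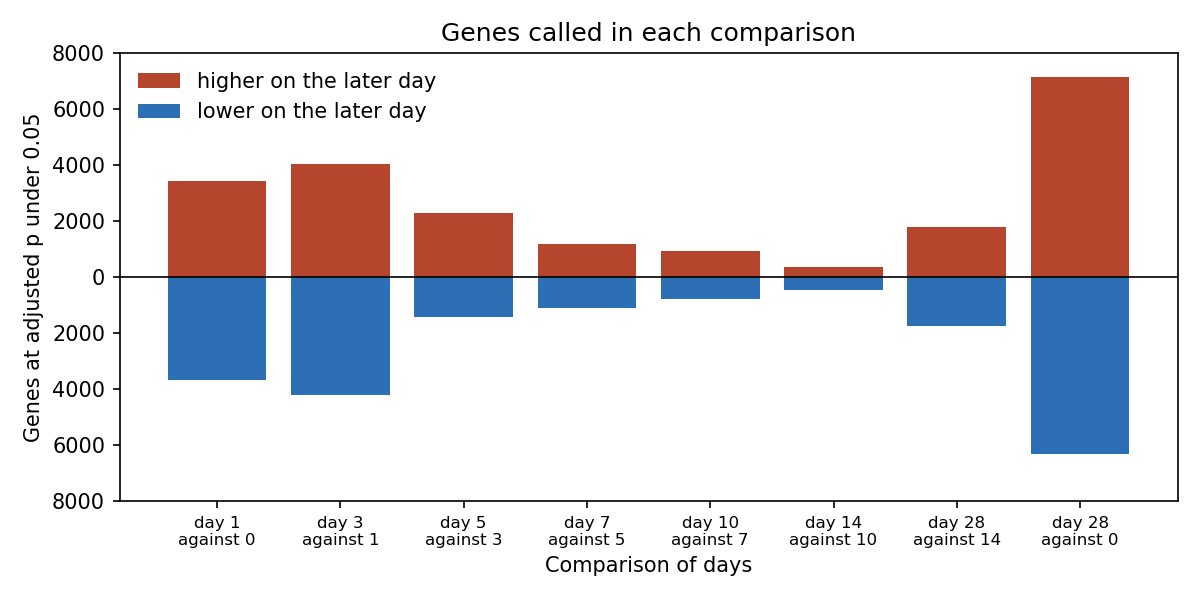
Bars give the number of genes called higher (above 0) and lower (below 0) in each of the 8 comparisons at adjusted p under 0.05 in edgeR. The counts run from 364 higher and 469 lower for day 14 against day 10 to 7144 higher and 6320 lower for day 28 against day 0.

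**Figure D3:**
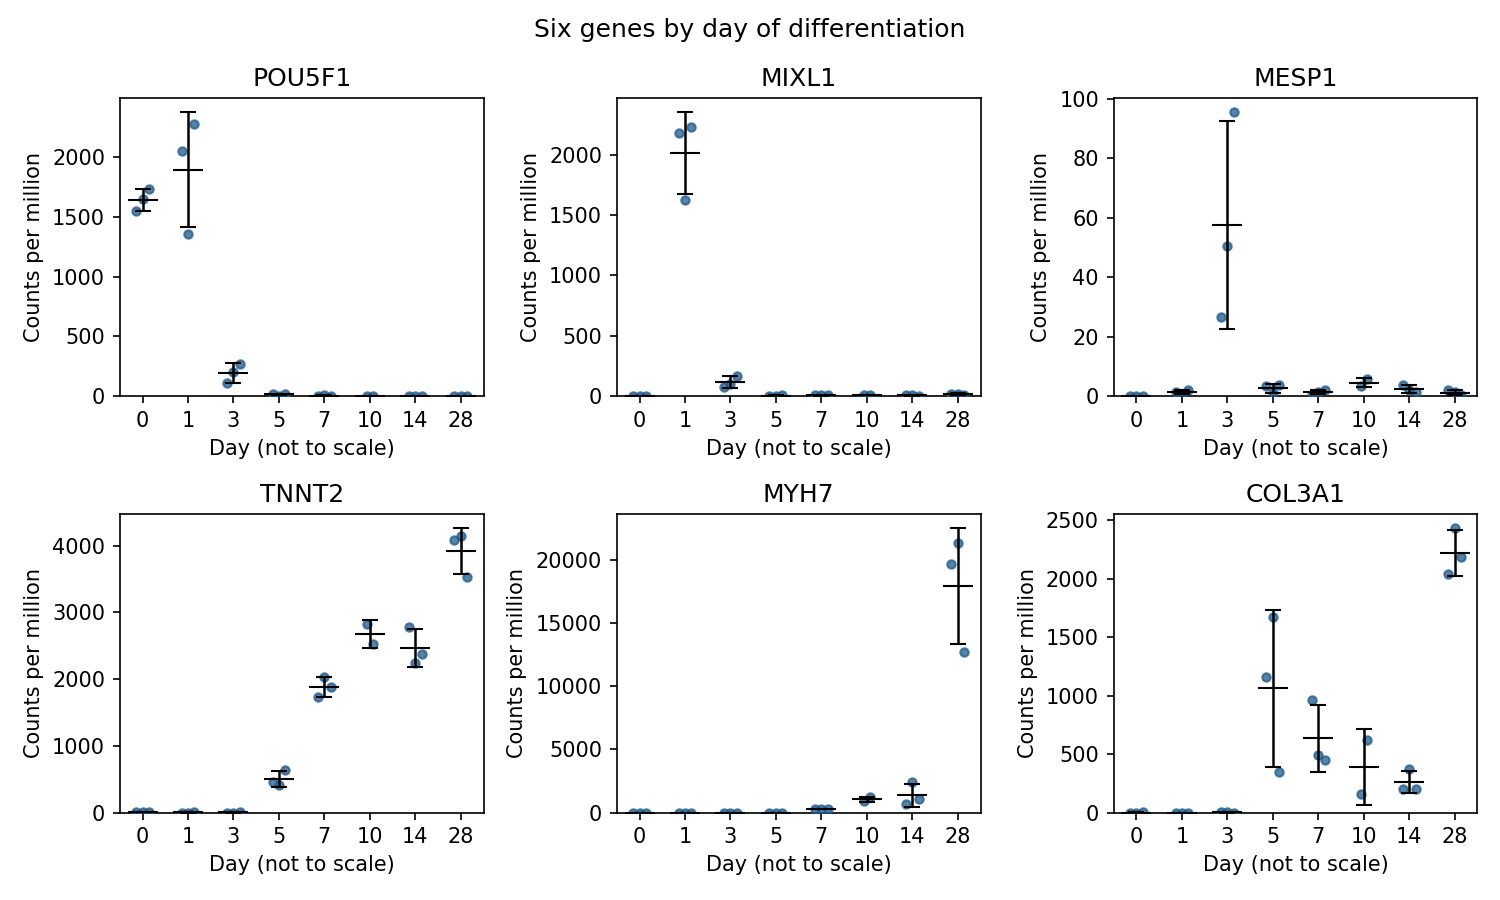
Panels show POU5F1, MIXL1, MESP1, TNNT2, MYH7 and COL3A1 in CPM against day of differentiation (days evenly spaced, not to scale), with points for libraries and bars for mean ± SD. MIXL1 is highest at day 1 (2013 CPM), MESP1 at day 3 (57.5 CPM) and MYH7 at day 28 (17920 CPM).

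The series title names LPIN1, and CLIPPER, a symbol not in the annotation that was not identified or analysed. LPIN1 (ENSG00000134324) encodes lipin-1, a phosphatidate phosphatase and transcriptional coactivator. It lies on the plus strand of chromosome 2, from 11677595 to 11827409 in GRCh38, and the counts cover its annotated exons. Its level was 17.0 ± 0.727 CPM at day 0 and 16.3 ± 2.83 at day 1. LPIN1 then rose to 61.6 ± 16.4 at day 3 (log2 change 1.92, SE 0.28, adjusted p = 6.3e-06). It fell to 22.7 ± 10.2 at day 5 (log2 change -1.42, SE 0.27, adjusted p = 0.000424). With only the libraries of days 3 and 5 in the fit, that fall no longer passed (log2 change -1.46, SE 0.47, adjusted p = 0.0763). LPIN1 stood at 35.4 ± 3.78 CPM at day 7, 64.4 ± 18.5 at day 10, 92.8 ± 4.93 at day 14 and 89.3 ± 5.94 at day 28. The 4 steps after day 5 did not pass the edgeR test, with log2 changes of 0.61, 0.87, 0.53 and -0.05 and adjusted p of 0.170, 0.0733, 0.333 and 0.933. The step from day 5 to day 7 was 1.00 (adjusted p = 0.0133) without day 5 replicate 2 and 0.31 (adjusted p = 0.392) without day 5 replicate 3. The step to day 10 was 0.52 without day 10 replicate 1, and the step to day 14 was 0.23 without day 10 replicate 2. Across the whole course LPIN1 rose (day 28 against day 0, log2 change 2.39, SE 0.28, adjusted p = 5.74e-08).

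**Figure D4:**
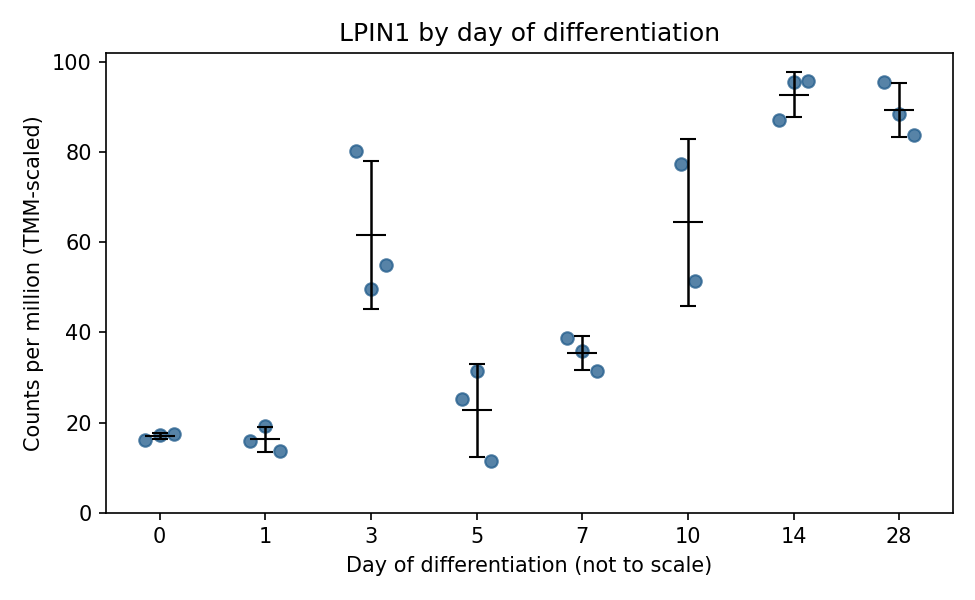
LPIN1 in CPM against day of differentiation (days evenly spaced, not to scale), with a point for each library and bars for mean ± SD (3 libraries per day, 2 at day 10). The day 3 libraries lie above those of days 1 and 5, and the means rise from 22.7 CPM at day 5 to 92.8 at day 14.

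LPIN2 and LPIN3, the other lipin genes, were measured as well. LPIN2 went from 32.3 ± 0.325 CPM at day 0 to 61.4 ± 1.96 at day 28 (log2 change 0.93, adjusted p = 0.00272), and no single step was called for it. LPIN3 rose at day 1 (log2 change 1.23) and over the whole course (2.02). Its change from day 14 to day 28, 0.94 (adjusted p = 0.0427), no longer passed without day 14 replicate 1 (0.0526), 2 (0.119) or 3 (0.102), or without day 28 replicate 1 (0.106) or 2 (0.0989). Nor did it pass with library totals alone (0.73, adjusted p = 0.0991) or upper-quartile factors (0.82, adjusted p = 0.102). Each of 4 genes annotated inside LPIN1 had few counts over all 23 libraries: 16 for ENSG00000203643, 131 for ENSG00000228496, 17 for ENSG00000230790 and 13 for MIR548S, against 13195 for LPIN1. The nearest genes on either side, ENSG00000276411 and MIR3681HG, had 1 and 27 counts. With the strand setting not stated, counts of these and of other antisense or overlapping genes are uncertain.

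Day 1 against day 0 asks what the first day of differentiation changed. Genes of the primitive streak rose from low levels. MIXL1, a homeobox gene of the streak, reached 2013 ± 338 CPM from 1.32 ± 0.401 (log2 change 10.55, adjusted p = 4.73e-14). The T-box genes TBXT and EOMES rose by 10.96 and 10.41, to 512 ± 86.5 and 609 ± 69.7 CPM. DKK1 and DKK4, secreted antagonists of Wnt signalling, rose to 801 ± 70.3 and 502 ± 63.4 CPM (log2 changes 10.64 and 11.03). SP5, a target of Wnt signalling, and the caudal gene CDX1 rose by 10.51 and 10.76. EVX1 was at 0 counts in every day 0 library and at 89.4 CPM at day 1, at least 1694-fold higher against a floor of 3 counts over the 3 libraries. CDX2 and MSGN1, with 2 counts and 1 count over the 3 day 0 libraries, stood at 48.3 ± 12.6 and 22.2 ± 3.65 CPM at day 1. The genes that fell most were DGKK, a diacylglycerol kinase (log2 change -5.80), SORBS2 (-5.38), RIPOR2 (-4.95), TRIML2 (-4.74), KLHDC7A (-4.42) and IDO1, an enzyme of tryptophan breakdown (-4.18, from 66.4 ± 2.83 to 3.66 ± 0.422 CPM). SHISA2, LNCPRESS1, LINGO1 and CNTN1 had log2 changes between -3.68 and -3.83.

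Of the primitive streak and mesendoderm list, 13 of 15 tested members rose and 2 did not pass (13 higher and 1 lower adjusted over the list alone). Its median was far above that of other genes (median log2 change 6.40, camera adjusted p = 5.83e-57). NODAL rose to 440 CPM (log2 change 5.95), GSC by 9.51 and WNT3 by 4.85. The cardiac mesoderm list moved up as well (median log2 change 2.48, camera adjusted p = 1.58e-08). There 9 of 14 tested members rose and 5 did not pass (9 higher adjusted over the list alone), led by MSX1 (6.37), APLNR (6.08) and FOXC1 (4.77). Among cardiac transcription factors, 4 of 17 tested members rose, 1 fell and 12 did not pass (4 higher and 1 lower adjusted over the list alone), with GATA4 and GATA6 at log2 changes of 8.34 and 8.01 (median log2 change 0.29, or 0.23 with all-zero members at their bound, camera adjusted p = 0.00922, adjusted p = 0.183 with an estimated correlation). The pluripotency list moved down (median log2 change -0.80, camera adjusted p = 1.76e-07). In all 9 of 17 tested members fell, 1 rose and 7 did not pass (1 higher and 9 lower adjusted over the list alone). SOX2 fell from 209 ± 3.20 to 23.7 ± 4.67 CPM (log2 change -3.14), and TERF1, USP44, PRDM14 and L1TD1 had log2 changes between -2.82 and -3.30. POU5F1 was at 1642 ± 94.1 CPM at day 0 and 1895 ± 479 at day 1 (log2 change 0.21, adjusted p = 0.759).

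The replication-dependent histones are multi-copy genes, so their single levels are uncertain. Of these, 28 of 29 tested members rose and 1 did not pass (28 higher adjusted over the list alone) (median log2 change 1.23, camera adjusted p = 1.24e-08, adjusted p = 0.398 with an estimated correlation), with H2AC11 at 1.62 and H1-3 at 1.51. In the cell cycle list 9 of 35 tested members fell, 2 rose and 24 did not pass (2 higher and 9 lower adjusted over the list alone), and its median (0.06), mean (-0.30) and test (downward, adjusted p = 0.379) differed in sign. TOP2A, a topoisomerase, fell (log2 change -2.40). Nuclear genes of oxidative phosphorylation moved up as a list (median log2 change 0.50, camera adjusted p = 0.000481, adjusted p = 0.523 with an estimated correlation). There 25 of 74 tested members rose, 1 fell and 48 did not pass (27 higher and 1 lower adjusted over the list alone), among them ATP5PD (1.23) and COX6B1 (0.85). The mitochondrially encoded messenger RNAs did so too (median log2 change 0.75, camera adjusted p = 0.00740, adjusted p = 0.596 with an estimated correlation). There 7 of 13 tested members rose and 6 did not pass (13 higher adjusted over the list alone), with MT-ND3 at 0.84. Of the stress response genes, 9 of 16 tested members rose, 2 fell and 5 did not pass (10 higher and 2 lower adjusted over the list alone), with CDKN1A, a cyclin-dependent kinase inhibitor, at 3.19 and GDF15 at 2.05 (median log2 change 0.72, camera adjusted p = 0.00283, adjusted p = 0.234 with an estimated correlation). CPT1A, which carries fatty acids into mitochondria, rose from 11.1 ± 1.39 to 108 ± 18.7 CPM (log2 change 3.29). The calcium handling and ion channel list moved down (median log2 change -0.67, camera adjusted p = 0.0354, adjusted p = 0.0698 with an estimated correlation, adjusted p = 0.0765 without day 1 replicate 2). There 9 of 26 tested members fell, 2 rose and 15 did not pass (2 higher and 9 lower adjusted over the list alone), with RYR2 at -2.04. Among markers of other cell types, endoderm and liver moved up (median log2 change 0.45, camera adjusted p = 0.00368, adjusted p = 0.456 with an estimated correlation). There 4 of 14 tested members rose, 1 fell and 9 did not pass (4 higher and 1 lower adjusted over the list alone), with FOXA2 at 41.3 CPM. The skeletal muscle list had 3 tested members (median log2 change 1.68, camera adjusted p = 0.0183, adjusted p = 0.0769 with an estimated correlation), of which MYF6 was called (log2 change 5.16) and the others did not pass.

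In all, edgeR called 3413 genes higher and 3668 lower at day 1, of which 1948 and 2842 changed at least 2-fold. The counts moved by over 1.5 times when a library was left out: 2197 higher without day 0 replicate 1, 2166 higher and 2179 lower without day 0 replicate 2, 2215 and 1913 without day 1 replicate 1, and 1992 and 1952 without day 1 replicate 3.

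Day 3 against day 1 asks what changed between mesendoderm and cardiac mesoderm. HAND1, a transcription factor of the early heart, stood at 210 ± 48.3 CPM at day 3 and had 2 counts over the day 1 libraries. BMPER, which binds bone morphogenetic proteins, rose to 186 ± 62.4 CPM (log2 change 8.50, adjusted p = 9.25e-14), ITGA8, an integrin subunit, to 122 ± 31.6 (9.96), and HAPLN1, a hyaluronan link protein, to 345 ± 246 (9.02). RASGRP3 and SEMA6D rose by 8.99 and 8.66. CFC1, GASK1B and KCNA1, with 1 count, 2 counts and 3 counts over the day 1 libraries, stood at 39.0 ± 13.1, 28.7 ± 15.7 and 34.7 ± 11.2 CPM. The ligand NODAL fell from 440 ± 87.4 to 3.73 ± 0.716 CPM (log2 change -6.88, adjusted p = 4.63e-14), and the pluripotency factor NANOG from 162 ± 28.5 to 1.95 ± 1.28 (-6.44). THBS2, a thrombospondin, PCSK1, a prohormone convertase, GDF3 and DKK4 fell, with log2 changes of -7.36, -6.93, -6.91 and -6.85. HPAT5, TNFRSF8, GAP43 and CRYBB1 had log2 changes of -6.04, -5.86, -5.72 and -5.29.

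The cardiac mesoderm list moved furthest (median log2 change 5.19, camera adjusted p = 1.8e-25). In all 12 of 14 tested members rose and 2 did not pass (12 higher and 1 lower adjusted over the list alone). MESP1, a marker of cardiac mesoderm, rose from 1.41 ± 0.697 to 57.5 ± 35.0 CPM (log2 change 5.40), PDGFRA by 6.38 and BMP4 by 6.06. Of the cardiac transcription factors, 13 of 17 tested members rose, 1 fell and 3 did not pass (14 higher and 1 lower adjusted over the list alone), with ISL1 at 6.28, TBX20 at 4.84 and MYOCD at 3.63 (median log2 change 2.67, camera adjusted p = 9.98e-10). For sarcomere genes 11 of 26 tested members rose, 4 fell and 11 did not pass (12 higher and 5 lower adjusted over the list alone), the muscle light chain MYL4 reaching 16.5 CPM and ACTC1 falling to 9.96 (median log2 change 0.72, camera adjusted p = 0.0138, adjusted p = 0.197 with an estimated correlation). Calcium handling and ion channels moved up (median log2 change 0.87, camera adjusted p = 0.0151). There 12 of 26 tested members rose, 3 fell and 11 did not pass (12 higher and 3 lower adjusted over the list alone), with KCNA5 at 3.88 and KCNH2 at 2.36. Of the long non-coding RNAs, 8 of 12 tested members rose, 2 fell and 2 did not pass (9 higher and 2 lower adjusted over the list alone), with H19 at 4.74 and MIAT at -2.86 (median log2 change 2.47, or 2.44 with all-zero members at their bound, camera adjusted p = 0.00747, adjusted p = 0.0740 with an estimated correlation). The primitive streak list turned down (median log2 change -2.66, camera adjusted p = 6.97e-10, adjusted p = 0.0563 with an estimated correlation). There 11 of 15 tested members fell, 3 rose and 1 did not pass (3 higher and 11 lower adjusted over the list alone), with TBXT at -4.99 and MIXL1 at -4.09, while LHX1 and TBX6 rose by 3.71 and 2.06. From the pluripotency list 14 of 17 tested members fell and 3 did not pass (14 lower adjusted over the list alone), POU5F1 going from 1895 ± 479 to 194 ± 81.0 CPM (median log2 change -1.84, camera adjusted p = 8.81e-13).

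In nuclear oxidative phosphorylation 48 of 74 tested members fell, 1 rose and 25 did not pass (1 higher and 53 lower adjusted over the list alone), with ATP5PD at -1.94 and ATP5MC1 at -1.59 (median log2 change -0.80, camera adjusted p = 8.52e-09, adjusted p = 0.238 with an estimated correlation). The tricarboxylic acid cycle (median log2 change -0.72, camera adjusted p = 0.00119, adjusted p = 0.0598 with an estimated correlation) had OGDHL at -2.74 and PDHB at -1.33, and 10 of 18 tested members fell and 8 did not pass (11 lower adjusted over the list alone). From the glycolysis list 6 of 19 tested members fell and 13 did not pass (11 lower adjusted over the list alone), with HK1, a hexokinase, at -1.83 (median log2 change -0.73, camera adjusted p = 0.0126, adjusted p = 0.596 with an estimated correlation, adjusted p = 0.112 without day 3 replicate 1). Fatty acid oxidation moved down (median log2 change -0.47, camera adjusted p = 0.0354, adjusted p = 0.193 with an estimated correlation, adjusted p = 0.0555 without day 3 replicate 2). There 9 of 25 tested members fell, 3 rose and 13 did not pass (3 higher and 9 lower adjusted over the list alone) and CPT1A went back to 6.76 CPM. Of the histones, 13 of 29 tested members fell and 16 did not pass (14 lower adjusted over the list alone), with H3C1 at -2.10 (median log2 change -0.76, camera adjusted p = 3.62e-06, adjusted p = 0.516 with an estimated correlation). Among the lists of other cell types, endoderm and liver moved up (median log2 change 1.98, or 1.37 with all-zero members at their bound, camera adjusted p = 0.00922, adjusted p = 0.514 with an estimated correlation). There 6 of 14 tested members rose, 3 fell and 5 did not pass (6 higher and 3 lower adjusted over the list alone). SOX17, a transcription factor of endoderm and endothelium, was at 0 counts at day 1 and 121 ± 47.3 CPM at day 3, at least 1819-fold higher. Fibroblast and stroma moved up (median log2 change 1.51, or 1.49 with all-zero members at their bound, camera adjusted p = 0.0136, adjusted p = 0.387 with an estimated correlation, adjusted p = 0.0557 without day 1 replicate 2). There 7 of 14 tested members rose, 1 fell and 6 did not pass (7 higher and 1 lower adjusted over the list alone), PDGFRB rising by 4.96 and FN1, fibronectin, to 3261 CPM.

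The test called 4049 genes higher and 4227 lower at day 3, of which 3356 and 2696 changed at least 2-fold. With library totals alone as the scaling, 64.0% of the calls were higher, against 48.9% with TMM.

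Day 5 against day 3 asks what changed between cardiac mesoderm and progenitors. Sarcomere genes rose from low levels. TNNT2, cardiac troponin T, went from 1.28 ± 0.379 to 506 ± 118 CPM (log2 change 8.66, adjusted p = 8.16e-15), and MYH6, the alpha myosin heavy chain, to 751 ± 260 (9.08). UNC45B, a myosin chaperone, and SMYD1, a muscle methyltransferase, rose by 9.59 and 9.12, to 232 ± 56.7 and 191 ± 40.3 CPM. COL3A1, a fibrillar collagen, rose by 10.38 to 1060 ± 668 CPM and LUM, lumican, by 9.10 to 115 ± 118. XIRP1 and the natriuretic peptide gene NPPB rose by 8.49 and 8.15. TTR, the transport protein transthyretin, and WNT2, with 2 counts each over the day 3 libraries, stood at 209 ± 116 and 62.5 ± 32.9 CPM. STMN2 fell from 73.8 ± 25.2 to 0.631 ± 0.316 CPM (log2 change -7.06). WNT8A, NTS, LEFTY2, FGF17, NTN1, DRD2, MESP2 and TNFRSF11B had log2 changes between -4.92 and -5.52.

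Of the sarcomere list, 19 of 26 tested members rose and 7 did not pass (22 higher adjusted over the list alone) (median log2 change 4.20, camera adjusted p = 4.93e-58). ACTC1, cardiac actin, reached 2216 CPM, MYL7 702 and TPM1 2921, with log2 changes of 7.80, 7.03 and 5.13. Among cardiac transcription factors 11 of 17 tested members rose, 1 fell and 5 did not pass (11 higher and 1 lower adjusted over the list alone), with NKX2-5 at 7.89, TBX5 at 7.75, MEF2C at 6.90 and HAND2 at 6.23 (median log2 change 2.22, camera adjusted p = 9.83e-20). Calcium handling and ion channels moved up (median log2 change 0.38, camera adjusted p = 0.000288). In all 10 of 26 tested members rose, 6 fell and 10 did not pass (11 higher and 6 lower adjusted over the list alone). PLN, phospholamban, rose by 6.99 and RYR2, the ryanodine receptor, by 4.45. From the maturation list 6 of 17 tested members rose, 1 fell and 10 did not pass (6 higher and 3 lower adjusted over the list alone), with PYGM at 2.85 (median log2 change 0.52, camera adjusted p = 0.0123, adjusted p = 0.387 with an estimated correlation, adjusted p = 0.0515 without day 3 replicate 1 and 0.0644 without day 5 replicate 3). Of the long non-coding RNAs, 7 of 12 tested members rose and 5 did not pass (7 higher and 1 lower adjusted over the list alone), H19 going from 7.46 to 419 CPM (median log2 change 1.44, camera adjusted p = 1.47e-07). The primitive streak list fell again (median log2 change -3.50, camera adjusted p = 4.87e-19). There 12 of 15 tested members fell, 1 rose and 2 did not pass (1 higher and 12 lower adjusted over the list alone), EOMES from 150 to 7.07 CPM. In the cardiac mesoderm list 8 of 14 tested members fell and 6 did not pass (1 higher and 10 lower adjusted over the list alone), with MESP1 at -4.51 and DLL3 at -3.21 (median log2 change -1.16, camera adjusted p = 2.25e-08). Of the pluripotency genes, 8 of 17 tested members fell, 1 rose and 8 did not pass (2 higher and 10 lower adjusted over the list alone), with POU5F1 at -3.65 (median log2 change -1.04, or -0.96 with all-zero members at their bound, camera adjusted p = 0.000134).

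Smooth muscle markers rose as a list (median log2 change 2.48, camera adjusted p = 2.23e-12). There 6 of 8 tested members rose and 2 did not pass (6 higher and 1 lower adjusted over the list alone), ACTA2 reaching 97.9 CPM and TAGLN 256. In fibroblast and stroma 8 of 14 tested members rose, 1 fell and 5 did not pass (8 higher and 2 lower adjusted over the list alone), with COL1A1 at 4.40 (median log2 change 1.79, camera adjusted p = 5.39e-06, adjusted p = 0.0889 with an estimated correlation). Epicardial markers moved up (median log2 change 2.74, camera adjusted p = 1.46e-05). There 5 of 8 tested members rose, 1 fell and 2 did not pass (6 higher and 1 lower adjusted over the list alone), TBX18 reaching 16.1 CPM and WT1 15.6. Endothelial markers also rose (median log2 change 2.12, camera adjusted p = 0.000143). There 7 of 13 tested members rose, 1 fell and 5 did not pass (7 higher and 1 lower adjusted over the list alone), with TEK at 3.64 and CDH5 by 2.29. For endoderm and liver 9 of 14 tested members rose, 2 fell and 3 did not pass (10 higher and 2 lower adjusted over the list alone), APOA1 reaching 73.9 CPM and SOX17 falling to 7.45 (median log2 change 2.98, camera adjusted p = 2.22e-06, adjusted p = 0.193 with an estimated correlation).

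The numbers called were 2290 higher and 1408 lower, of which 1863 and 1188 changed at least 2-fold; without day 5 replicate 2 the lower count was 4579, and with only the libraries of the 2 days the counts were 846 and 556. Other splits of the 6 libraries called up to 6275 genes, pointing to structure besides the day.

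Day 7 against day 5 compares 2 days that the labels give the same stage, cardiac progenitors. Sarcomere genes rose further. MYL3, a ventricular light chain, went from 4.39 ± 1.61 to 722 ± 103 CPM (log2 change 7.42, adjusted p = 2e-14), and MYH7, the beta myosin heavy chain, from 2.16 ± 0.643 to 291 ± 23.8 (7.15). CKM, muscle creatine kinase, rose by 7.09 and MYOM1, myomesin-1, by 6.13. CGA, the common chain of the glycoprotein hormones, rose by 8.31 to 122 ± 33.5 CPM. The protease inhibitor A2M, the laminin gene LAMA4, the complement gene MASP1 and OIT3 rose by 6.71, 6.27, 6.24 and 5.95. NPPA, natriuretic peptide A, rose to 142 ± 13.2 CPM (log2 change 5.15). GAP43 and HOXB1 fell most (log2 changes -4.68 and -4.19), and CCND2, cyclin D2, fell from 540 ± 278 to 78.1 ± 16.4 CPM (-2.79). VRTN, SMOC2, PTGIS, LRP1B and SVEP1 had log2 changes between -2.66 and -3.14. DDR2, a collagen receptor, fell (log2 change -3.53, or -1.85 (adjusted p = 0.00198) without day 5 replicate 2). KCNJ3 fell too (log2 change -3.04, or -1.82 (adjusted p = 0.00376) without day 5 replicate 2).

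Of the sarcomere genes, 24 of 26 tested members rose and 2 did not pass (24 higher adjusted over the list alone) (median log2 change 2.50, or 2.27 with all-zero members at their bound, camera adjusted p = 4.94e-77). MYH6 reached 4817 ± 757 CPM, TNNC1 778 and ACTN2 288. In calcium handling and ion channels 16 of 26 tested members rose, 2 fell and 8 did not pass (17 higher and 2 lower adjusted over the list alone), with TRDN, triadin, at 4.37, SLC8A1, the sodium-calcium exchanger, at 2.79 and KCNIP2 at 5.40 (median log2 change 1.53, camera adjusted p = 2.01e-21). The maturation list moved up (median log2 change 2.90, or 2.86 with all-zero members at their bound, camera adjusted p = 3.33e-38). There 13 of 17 tested members rose and 4 did not pass (13 higher adjusted over the list alone), with MB, myoglobin, at 3.75 and PYGM at 3.14. Fatty acid oxidation rose as a list (median log2 change 0.55, camera adjusted p = 6.97e-10). There 7 of 25 tested members rose and 18 did not pass (9 higher adjusted over the list alone), among them FABP3 (2.90), CPT1A (2.13) and ACSL1 (2.06). PPARGC1A, a coactivator of mitochondrial gene programs, rose from 8.61 ± 7.67 to 46.6 ± 7.29 CPM (log2 change 2.35). In oxidative phosphorylation 5 of 74 tested members rose and 69 did not pass (5 higher adjusted over the list alone) (median log2 change 0.21, camera adjusted p = 0.00167, adjusted p = 0.585 with an estimated correlation, adjusted p = 0.0659 without day 5 replicate 2). In the tricarboxylic acid cycle 3 of 18 tested members rose and 15 did not pass (4 higher adjusted over the list alone) (median log2 change 0.32, camera adjusted p = 0.0173, adjusted p = 0.169 with an estimated correlation). COX7B rose by 0.95 and IDH3A by 1.06, calls that were lost with only the libraries of the 2 days (adjusted p = 0.181 and 0.135). Of the cardiac transcription factors 3 of 17 tested members rose and 14 did not pass (7 higher and 1 lower adjusted over the list alone), IRX4, a ventricular factor, going from 0.0232 to 15.8 CPM (median log2 change 0.24, camera adjusted p = 0.00162, adjusted p = 0.110 with an estimated correlation).

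The cell cycle list fell (median log2 change -1.27, camera adjusted p = 6.82e-18). There 24 of 35 tested members fell and 11 did not pass (30 lower adjusted over the list alone). E2F1, CDC6 and MCM5 had log2 changes of -2.44, -1.82 and -1.61. Of the histones, 21 of 29 tested members fell and 8 did not pass (26 lower adjusted over the list alone) (median log2 change -1.20, camera adjusted p = 1.77e-11, adjusted p = 0.305 with an estimated correlation). H2BC10 changed by -1.51, or by -0.90 (adjusted p = 0.0416) without day 5 replicate 3, and its call was lost with only the libraries of the 2 days (adjusted p = 0.0645). Pluripotency genes continued down (median log2 change -0.94, camera adjusted p = 3.77e-05). There 7 of 17 tested members fell, 1 rose and 9 did not pass (1 higher and 9 lower adjusted over the list alone), with ZFP42 at -1.49, while SOX2 rose from 2.04 to 9.28 CPM. In the cardiac mesoderm list 6 of 14 tested members fell and 8 did not pass (7 lower adjusted over the list alone), with SNAI2 at -2.43 (median log2 change -0.86, camera adjusted p = 0.000181). Endothelial markers rose beside the sarcomere genes (median log2 change 2.86, camera adjusted p = 9.5e-19). There 9 of 13 tested members rose and 4 did not pass (9 higher adjusted over the list alone), CDH5 going from 6.09 to 61.1 CPM and PLVAP from 4.72 to 48.5. Smooth muscle markers rose as a list (median log2 change 0.34, camera adjusted p = 0.00246, adjusted p = 0.0778 with an estimated correlation). There 3 of 8 tested members rose and 5 did not pass (3 higher and 1 lower adjusted over the list alone), ACTA2 reaching 733 CPM. Of the epicardial markers, 4 of 8 tested members fell and 4 did not pass (4 lower adjusted over the list alone), with TCF21 at -2.70 (median log2 change -1.39, camera adjusted p = 0.0114, adjusted p = 0.193 with an estimated correlation, adjusted p = 0.0823 without day 5 replicate 2).

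At day 7, 1184 genes were higher and 1117 lower, of which 1069 and 830 changed at least 2-fold. The higher count was 2227 without day 5 replicate 2, and the lower count was 1808 without day 5 replicate 3, 583, 432 and 544 without day 7 replicates 1, 2 and 3, and 707 with library totals alone, where 67.9% of calls were higher against 51.5%.

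Day 10 against day 7 asks what changed on passing from progenitors to cells the labels call cardiomyocytes, with 2 libraries at day 10. FHL2, a LIM-domain protein of the heart, went from 57.4 ± 8.09 to 529 ± 134 CPM (log2 change 3.20, adjusted p = 4.39e-07) and ADPRHL1 from 21.2 ± 1.23 to 243 ± 5.55 (3.52). AKAP6, a scaffold of protein kinase A, FBXO40, a muscle F-box protein, and GRIA1, a glutamate receptor subunit, rose by 3.12, 3.09 and 4.48. SERPINA1, alpha-1 antitrypsin, went from 57.6 ± 1.58 to 1365 ± 1148 CPM (log2 change 4.57), ITIH2 rose by 5.54 and AHSG by 6.81, or by 4.40 (adjusted p = 0.00186) without day 10 replicate 2. Genes that fell were led by IHH, Indian hedgehog (-4.96), ALPL, an alkaline phosphatase (-3.81), NPY, neuropeptide Y (-3.63, from 229 ± 34.9 to 18.5 ± 2.41 CPM) and OIT3 (-3.47). RIPPLY3, ELAPOR1, CCKBR, COL9A2, BAALC and GRAP2 had log2 changes between -2.78 and -3.35. NPPA rose from 142 ± 13.2 to 673 ± 2.85 CPM (log2 change 2.24).

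Of the sarcomere list, 9 of 26 tested members rose and 17 did not pass (13 higher adjusted over the list alone) (median log2 change 0.73, camera adjusted p = 5.78e-11), among them MYOZ2 (2.75), CSRP3 (2.13), ACTN2 (1.91) and MYH7 (1.86). In calcium handling and ion channels 8 of 26 tested members rose and 18 did not pass (9 higher adjusted over the list alone) (median log2 change 0.54, camera adjusted p = 0.000181). CASQ2, calsequestrin, changed by 2.41, or by 1.88 (adjusted p = 0.210) without day 10 replicate 1, and its call also ended without the 4 libraries highest on the within-day axis (1.88, adjusted p = 0.0570). The maturation list moved up (median log2 change 0.85, camera adjusted p = 5.62e-06, adjusted p = 0.0949 with an estimated correlation). There 6 of 17 tested members rose and 11 did not pass (8 higher adjusted over the list alone), with TCAP at 2.06. In oxidative phosphorylation 14 of 74 tested members rose and 60 did not pass (24 higher adjusted over the list alone) (median log2 change 0.36, camera adjusted p = 1.71e-07, adjusted p = 0.305 with an estimated correlation), ATP5PO changing by 1.19, or by 0.90 (adjusted p = 0.193) without day 10 replicate 1. Of the tricarboxylic acid cycle genes 2 of 18 tested members rose and 16 did not pass (8 higher adjusted over the list alone) (median log2 change 0.62, camera adjusted p = 0.000224). Of the fatty acid oxidation genes 3 of 25 tested members rose and 22 did not pass (7 higher adjusted over the list alone) (median log2 change 0.52, camera adjusted p = 0.00335, adjusted p = 0.0741 with an estimated correlation, adjusted p = 0.0659 without day 10 replicate 1). In glycolysis 2 of 19 tested members rose and 17 did not pass (13 higher adjusted over the list alone), LDHA, lactate dehydrogenase A, going from 447 ± 18.6 to 2055 ± 273 CPM (log2 change 2.20), with the list at median log2 change 0.75, camera adjusted p = 7.97e-07, adjusted p = 0.236 with an estimated correlation. PPARGC1A changed by 1.41, a call that ended without day 7 replicate 1 (1.30, adjusted p = 0.116), day 7 replicate 2 (1.47, adjusted p = 0.0739), day 7 replicate 3 (1.25, adjusted p = 0.142) or day 10 replicate 1 (0.75, adjusted p = 0.607). It also ended with the replicate number as a block (1.22, adjusted p = 0.0619), with library totals alone (1.19, adjusted p = 0.0736) and without the 4 libraries highest on the within-day axis (0.77, adjusted p = 0.0748). From the stress response list 4 of 16 tested members rose and 12 did not pass (5 higher adjusted over the list alone), with CDKN1A at 2.75 and GDF15 at 2.25 (median log2 change 0.43, camera adjusted p = 0.0151, adjusted p = 0.357 with an estimated correlation, adjusted p = 0.134 without day 10 replicate 2).

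Cell cycle genes fell further (median log2 change -0.50, camera adjusted p = 5.27e-06, adjusted p = 0.306 with an estimated correlation). There 8 of 35 tested members fell and 27 did not pass (12 lower adjusted over the list alone), with MCM2 at -2.01. Of the histones, 17 of 29 tested members fell and 12 did not pass (25 lower adjusted over the list alone), H2BC14 going from 70.8 to 14.2 CPM (median log2 change -1.40, camera adjusted p = 5.59e-17, adjusted p = 0.192 with an estimated correlation). In the pluripotency list 6 of 17 tested members fell and 11 did not pass (6 lower adjusted over the list alone), with ZFP42 at -2.12 and DNMT3B at -1.61 (median log2 change -0.74, camera adjusted p = 2.06e-05). In cardiac mesoderm 2 of 14 tested members fell and 12 did not pass (1 higher and 5 lower adjusted over the list alone) (median log2 change -0.69, camera adjusted p = 0.0322, adjusted p = 0.197 with an estimated correlation, adjusted p = 0.0943 without day 7 replicate 1 and 0.144 without day 10 replicate 1). Endothelial markers turned down (median log2 change -1.03, camera adjusted p = 1.86e-06). There 4 of 13 tested members fell and 9 did not pass (1 higher and 7 lower adjusted over the list alone), with VWF, von Willebrand factor, at -3.08. The endoderm and liver list did not pass as a list (median log2 change -0.57, camera adjusted p = 0.251). In it 5 of 14 tested members fell, 3 rose and 6 did not pass (3 higher and 6 lower adjusted over the list alone), with SERPINA1 at 4.57 and ALB at 4.11.

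This step had 928 genes higher and 778 lower, of which 801 and 735 changed at least 2-fold. The counts of higher and lower genes were 446 and 559 without day 7 replicate 1, 420 and 544 without replicate 2, 375 and 399 without replicate 3, 202 and 90 without day 10 replicate 1, 479 and 504 without day 10 replicate 2, and 597 and 1270 with library totals alone.

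Day 14 against day 10 compares days that share the cardiomyocyte label. SPHKAP, an anchoring protein of protein kinase A found in heart, rose from 5.55 ± 0.172 to 151 ± 30.1 CPM (log2 change 4.76, adjusted p = 2.12e-06), MLIP, a lamin-interacting protein of muscle, to 85.6 ± 15.4 (3.14), and POSTN, periostin, to 53.8 ± 16.8 (3.22). PLCXD3 and ALDH1A1 rose by 2.94 and 3.02. The calls of AFP, APOB and ABCC2 ended without 1 library. AFP, alpha-fetoprotein, changed by 3.32, or by 2.60 (adjusted p = 0.127) without day 10 replicate 1, APOB by 2.94, or by 2.50 (adjusted p = 0.0909) without day 10 replicate 1, and ABCC2 by 3.31, or by 2.87 (adjusted p = 0.0513) without day 10 replicate 1. Without the 4 libraries highest on the within-day axis, AFP changed by 2.68. COL14A1 changed by 2.82, a call that ended without day 10 replicate 1 (2.80, adjusted p = 0.0976), day 10 replicate 2 (2.75, adjusted p = 0.179) or day 14 replicate 3 (2.52, adjusted p = 0.0506). TECRL changed by 2.74, which did not pass without day 10 replicate 1 (3.34, adjusted p = 0.0544), day 10 replicate 2 (2.25, adjusted p = 0.296), day 14 replicate 1 (2.61, adjusted p = 0.0532) or day 14 replicate 3 (2.64, adjusted p = 0.0549). Both natriuretic peptide genes fell, NPPA from 673 ± 2.85 to 120 ± 32.8 CPM (log2 change -2.48) and NPPB from 316 ± 92.3 to 35.8 ± 35.4 (-3.14). CGA (-4.43), CBLN2 (-3.25), the apelin receptor APLNR (-2.90), tenascin-C, TNC (-2.79), skeletal actin, ACTA1 (-2.72) and GPR19 (-2.50) fell too.

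Most lists that moved at this step moved down. Of the histones, 22 of 29 tested members fell and 7 did not pass (28 lower adjusted over the list alone) (median log2 change -1.57, camera adjusted p = 1.25e-27, adjusted p = 0.0782 with an estimated correlation), H1-3 going from 154 to 34.4 CPM. In the cell cycle list 10 of 35 tested members fell and 25 did not pass (14 lower adjusted over the list alone) (median log2 change -0.79, camera adjusted p = 2.88e-13, adjusted p = 0.0785 with an estimated correlation), with BIRC5, survivin, at -2.12. Of the pluripotency genes, 6 of 17 tested members fell and 11 did not pass (6 lower adjusted over the list alone), LIN28A going from 313 to 62.3 CPM (median log2 change -0.94, camera adjusted p = 1.31e-07). In the primitive streak list 5 of 15 tested members fell and 10 did not pass (5 lower adjusted over the list alone), with FGF8 at -2.23 (median log2 change -1.49, or -0.66 with all-zero members at their bound, camera adjusted p = 2.87e-06, adjusted p = 0.167 with an estimated correlation). In cardiac mesoderm 2 of 14 tested members fell and 12 did not pass (2 lower adjusted over the list alone) (median log2 change -0.69, camera adjusted p = 8.11e-05). Glycolysis genes moved down as a list (median log2 change -0.83, camera adjusted p = 7.4e-07, adjusted p = 0.234 with an estimated correlation). There 3 of 19 tested members fell and 16 did not pass (9 lower adjusted over the list alone), with ENO1 at -1.34, a call that ended without day 10 replicate 2 (-1.29, adjusted p = 0.131) or day 14 replicate 3 (-1.24, adjusted p = 0.0842). Nuclear oxidative phosphorylation moved down slightly (median log2 change -0.30, camera adjusted p = 0.000561, adjusted p = 0.524 with an estimated correlation) although edgeR called 0 of its 74 members in either direction; at an unadjusted p under 0.05, 1 was higher and 8 were lower, and DESeq2 called 3 lower. Endothelial markers fell (median log2 change -1.61, camera adjusted p = 2.33e-11). There 6 of 13 tested members fell and 7 did not pass (10 lower adjusted over the list alone), with ESAM at -2.54. Smooth muscle markers fell as well (median log2 change -0.58, camera adjusted p = 2.28e-06). There 3 of 8 tested members fell and 5 did not pass (3 lower adjusted over the list alone), TAGLN going from 487 ± 83.4 to 75.9 ± 59.6 CPM and ACTA2 from 465 ± 43.8 to 85.8 ± 30.2. Only the long non-coding RNAs rose as a list (median log2 change 0.66, camera adjusted p = 0.000662). There 3 of 12 tested members rose and 9 did not pass (5 higher adjusted over the list alone), with LINC00881 at 2.43. The sarcomere list did not move as a list (median log2 change 0.03, camera adjusted p = 0.947, its test pointing down).

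Here 364 genes were higher and 469 lower, of which 352 and 447 changed at least 2-fold, and DESeq2 called 585 and 729. The edgeR counts were 99 and 351 without day 10 replicate 1, 65 and 121 without day 10 replicate 2, 170 and 206 without day 14 replicate 1, and 119 and 233 without day 14 replicate 3.

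Day 28 against day 14 asks what changed over the last 14 days in culture. The ventricular light chain MYL2 rose from 5.58 ± 4.49 to 327 ± 66.1 CPM (log2 change 5.88, adjusted p = 7.75e-08), HOPX, a homeodomain-only protein, from 3.24 ± 2.64 to 192 ± 27.3 (5.89), NRAP from 1.35 ± 0.901 to 75.6 ± 20.9 (5.80), and PDLIM3 from 30.0 ± 16.1 to 1260 ± 158 (5.39). MYH7 rose to 17920 ± 4566 CPM (log2 change 3.70) while MYH6 fell from 9709 ± 1594 to 1869 ± 418 (-2.38). FGF5, CRYBB1, PTX3, BRINP3, EYA4 and IL31RA rose by between 5.30 and 6.18 on the log2 scale. Among genes that fell were AHSG (-7.38), APOB (-6.84), transferrin, TF (-5.13), and plasminogen, PLG (-5.03). LIN28A, an RNA-binding protein of stem cells, fell from 62.3 ± 27.5 to 0.668 ± 0.319 CPM (log2 change -6.52). AKR1C2, AKR1C1, DUSP9 and TAFA4 had log2 changes between -4.66 and -6.58. NPPA and NPPB rose again, to 585 ± 77.6 and 711 ± 112 CPM (log2 changes 2.28 and 4.31).

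Of the sarcomere list, 15 of 26 tested members rose, 2 fell and 9 did not pass (18 higher and 2 lower adjusted over the list alone) (median log2 change 0.97, camera adjusted p = 1.01e-08), ACTC1 reaching 11120 CPM, TPM1 9547 and TNNC1 2258. In calcium handling and ion channels 10 of 26 tested members rose, 2 fell and 14 did not pass (11 higher and 3 lower adjusted over the list alone) (median log2 change 0.31, camera adjusted p = 0.0404, adjusted p = 0.0741 with an estimated correlation, adjusted p = 0.0690 without day 14 replicate 3 and 0.0770 without day 28 replicate 1), with PLN at 2.04 and KCNIP2 at -3.31. The maturation list went both ways: 7 of 17 tested members fell, 5 rose and 5 did not pass (5 higher and 7 lower adjusted over the list alone), and its median (-0.05), mean (0.12) and test (downward, camera adjusted p = 0.986) differed in sign. Fibroblast and stroma markers rose beside the sarcomere genes (median log2 change 2.29, camera adjusted p = 2.17e-16). There 13 of 14 tested members rose and 1 did not pass (14 higher adjusted over the list alone), COL3A1 going from 260 ± 96.4 to 2217 ± 196 CPM and FBN1, fibrillin-1, from 47.8 ± 19.1 to 404 ± 38.9. All 8 smooth muscle markers rose (median log2 change 2.38, camera adjusted p = 5.71e-16), CNN1 to 1022 CPM and TAGLN to 918. Endoderm and liver markers fell (median log2 change -2.12, camera adjusted p = 2.87e-08, adjusted p = 0.129 with an estimated correlation). There 10 of 14 tested members fell and 4 did not pass (10 lower adjusted over the list alone), AFP going from 1743 ± 1192 to 151 ± 68.2 CPM and APOA1 from 112 ± 75.2 to 11.3 ± 1.94. In endothelium 3 of 13 tested members fell, 1 rose and 9 did not pass (1 higher and 5 lower adjusted over the list alone), with CDH5 at -2.63 (median log2 change -0.82, camera adjusted p = 0.00922, adjusted p = 0.110 with an estimated correlation).

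Cell cycle genes moved up as a list (median log2 change 0.44, camera adjusted p = 0.000802, adjusted p = 0.486 with an estimated correlation, adjusted p = 0.0828 without day 14 replicate 1 and 0.144 without day 28 replicate 3). There 7 of 35 tested members rose and 28 did not pass (7 higher adjusted over the list alone), with MCM5 at 1.45 and PCNA at 1.12. Of the long non-coding RNAs, 2 of 12 tested members rose and 10 did not pass (3 higher and 1 lower adjusted over the list alone), H19 going from 137 to 940 CPM and LINC00881 from 26.0 to 307 (median log2 change 0.02, camera adjusted p = 0.0487, adjusted p = 0.193 with an estimated correlation, adjusted p = 0.0593 without day 14 replicate 1, 0.118 without day 14 replicate 2, 0.136 without day 28 replicate 1 and 0.0547 without day 28 replicate 2). Pluripotency genes fell further (median log2 change -1.40, camera adjusted p = 1.67e-05). There 8 of 17 tested members fell and 9 did not pass (8 lower adjusted over the list alone). In cardiac mesoderm 6 of 14 tested members fell, 1 rose and 7 did not pass (3 higher and 6 lower adjusted over the list alone), with KDR at -2.04 (median log2 change -1.02, camera adjusted p = 0.0176, adjusted p = 0.169 with an estimated correlation, adjusted p = 0.0591 without day 14 replicate 2). MFN2, a mitochondrial fusion protein, rose from 221 ± 19.5 to 548 ± 30.2 CPM (log2 change 1.31), and UQCRQ was the 1 called gene of the 74 in oxidative phosphorylation (1.09).

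edgeR called 1771 genes higher and 1730 lower, of which 1364 and 1434 changed at least 2-fold. The lower count was 1111 without day 14 replicate 3 and 972 without day 28 replicate 3, and 32.0% of calls were higher with library totals alone and 40.2% with upper-quartile factors, against 50.6%.

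Day 28 against day 0 compares the last day with the stem cells. MYH7 went from 0.0871 ± 0.0266 to 17920 ± 4566 CPM (log2 change 17.48, adjusted p = 5.12e-17), PLN to 3330 ± 462 (14.80) and MYL4 to 3253 ± 545 (14.77). MYBPC3, CSRP3 and XIRP1, with 1 count each over the day 0 libraries, stood at 1815 ± 209, 1427 ± 178 and 860 ± 55.7 CPM. TRIM63, a muscle ubiquitin ligase, MLIP, CKM and HOPX were at 0 counts at day 0 and at 211, 207, 197 and 192 CPM at day 28, at least 4003-fold, 3920-fold, 3736-fold and 3636-fold higher. POU5F1, the stem cell factor OCT4, fell from 1642 ± 94.1 to 0.323 ± 0.217 CPM (log2 change -12.27), LIN28A from 3478 ± 107 to 0.668 ± 0.319 (-12.32). ZFP42, L1TD1, ESRG and ZSCAN10 had log2 changes between -10.60 and -11.85. VRTN, HPAT5 and PRDM14, with 1 count, 1 count and 2 counts over the day 28 libraries, had stood at 229 ± 12.3, 58.7 ± 2.25 and 83.6 ± 5.83 CPM at day 0. NKX1-2 went from 40.6 ± 0.692 CPM to 0 counts, at least 547-fold lower. NPPA rose by 12.82 and NPPB by 12.04.

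All 17 pluripotency genes fell (median log2 change -10.15, camera adjusted p = 7.09e-32), and all 26 sarcomere genes (median log2 change 10.01, camera adjusted p = 1.62e-52) and all 17 cardiac transcription factors (median log2 change 8.58, camera adjusted p = 1.5e-24) rose, over all genes tested and adjusted over the list alone. TNNT2 stood at 3920 ± 338 CPM, NKX2-5 at 221 ± 22.7 and GATA4 at 236 ± 21.1. Calcium handling and ion channels rose (median log2 change 3.52, camera adjusted p = 2.69e-14). There 23 of 26 tested members rose, 1 fell and 2 did not pass (23 higher and 1 lower adjusted over the list alone), RYR2 to 1722 CPM and SLC8A1 to 2694. Of the maturation list, 13 of 17 tested members rose and 4 did not pass (13 higher adjusted over the list alone) (median log2 change 4.74, camera adjusted p = 1.45e-12). From cardiac mesoderm 10 of 14 tested members rose, 3 fell and 1 did not pass (10 higher and 3 lower adjusted over the list alone) (median log2 change 3.82, camera adjusted p = 0.00315, adjusted p = 0.0928 with an estimated correlation). Of the long non-coding RNAs 10 of 12 tested members rose and 2 fell (10 higher and 2 lower adjusted over the list alone), with H19 at 10.16 (median log2 change 6.21, or 5.74 with all-zero members at their bound, camera adjusted p = 7.85e-07). In the cell cycle list 33 of 35 tested members fell and 2 did not pass (33 lower adjusted over the list alone), with CDC20 at -4.22 and RRM2 at -3.89 (median log2 change -2.94, camera adjusted p = 7.68e-13, adjusted p = 0.0631 with an estimated correlation). All 29 measured histone genes fell, also adjusted over the list alone (median log2 change -4.14, camera adjusted p = 3.53e-19, adjusted p = 0.169 with an estimated correlation).

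Mitochondrial and metabolic lists did not move as 1 block. PPARGC1A went from 2.22 ± 0.459 to 157 ± 17.1 CPM (log2 change 6.13), by way of 221 ± 74.3 at day 14, and ESRRG, an orphan nuclear receptor, rose by 5.03. Of the other biogenesis regulators TWNK, the mitochondrial helicase, PPRC1, SSBP1 and TFAM, which packages mitochondrial DNA, fell, with log2 changes of -2.10, -2.08, -1.28 and -1.28. In that list 9 of 16 tested members fell, 2 rose and 5 did not pass (3 higher and 10 lower adjusted over the list alone) (median log2 change -0.87, camera adjusted p = 0.356). Fatty acid oxidation rose (median log2 change 1.44, camera adjusted p = 0.000270). There 18 of 25 tested members rose, 1 fell and 6 did not pass (18 higher and 1 lower adjusted over the list alone), with CD36 at 6.61, FABP3 at 4.43 and PPARA at 3.02. The mitochondrially encoded messenger RNAs moved up (median log2 change 1.28, camera adjusted p = 0.0469, adjusted p = 0.713 with an estimated correlation, adjusted p = 0.0523 without day 0 replicate 3 and 0.0551 without day 28 replicate 3). There 10 of 13 tested members rose and 3 did not pass (10 higher adjusted over the list alone), with MT-ND5 at 1.70. In oxidative phosphorylation 22 of 74 tested members rose, 2 fell and 50 did not pass (18 higher adjusted over the list alone), with SDHA at 1.68 (median log2 change 0.27, camera adjusted p = 0.367). In mitochondrial dynamics 4 of 10 tested members rose and 6 did not pass (3 higher adjusted over the list alone), with MFN2 at 2.11 (median log2 change 0.67, camera adjusted p = 0.379). The tricarboxylic acid cycle had IDH3A at 2.33 and IDH2 at 2.25, and 10 of 18 tested members rose and 8 did not pass (10 higher adjusted over the list alone) (median log2 change 0.67, camera adjusted p = 0.106). From glycolysis 5 of 19 tested members rose, 3 fell and 11 did not pass (5 higher and 3 lower adjusted over the list alone), with PFKP at 2.58 (median log2 change 0.23, camera adjusted p = 0.797). In lipins and glycerolipid metabolism 7 of 26 tested members rose, 4 fell and 15 did not pass (7 higher and 4 lower adjusted over the list alone), with the phospholipase D gene PLD1 at 5.07 and the acyltransferase genes AGPAT3 and GPAT3 at 4.05 and 3.77 (median log2 change 0.26, camera adjusted p = 0.421). Of the stress response genes 9 of 16 tested members rose, 2 fell and 5 did not pass (9 higher and 2 lower adjusted over the list alone), CDKN1A reaching 631 ± 226 CPM and HMOX1 falling to 0.940 ± 0.207 (median log2 change 0.99, camera adjusted p = 0.144).

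Markers of other cell types at day 28 stood beside those of cardiomyocytes. Fibroblast and stroma (median log2 change 4.49, camera adjusted p = 1.09e-06, adjusted p = 0.0778 with an estimated correlation) had COL3A1 at 2217 CPM and FN1 at 4205, and 13 of 14 tested members rose and 1 fell (13 higher and 1 lower adjusted over the list alone). All 8 smooth muscle markers were higher than at day 0, also adjusted over the list alone (median log2 change 4.37, camera adjusted p = 1.4e-07). In endoderm and liver 11 of 14 tested members rose, 1 fell and 2 did not pass (11 higher and 1 lower adjusted over the list alone), with SERPINA1 at 691 ± 154 CPM (median log2 change 4.97, camera adjusted p = 0.00169, adjusted p = 0.419 with an estimated correlation). Of the epicardial markers 6 of 8 tested members rose, 1 fell and 1 did not pass (6 higher and 1 lower adjusted over the list alone), TBX18 reaching 24.2 CPM (median log2 change 3.64, or 2.44 with all-zero members at their bound, camera adjusted p = 0.105). The endothelial list had a median of -0.21, a mean of 0.46 and an upward test (camera adjusted p = 0.982), which differ in sign, and 5 of 13 tested members fell, 4 rose and 4 did not pass (4 higher and 5 lower adjusted over the list alone). In neural and ectoderm 3 of 6 tested members fell, 1 rose and 2 did not pass (1 higher and 3 lower adjusted over the list alone), with DCX at -4.54 (median log2 change -1.27, camera adjusted p = 0.477). In blood 2 of 4 tested members rose and 2 did not pass (2 higher adjusted over the list alone), with RUNX1 at 4.34 (median log2 change 2.34, camera adjusted p = 0.345). The primitive streak list (median log2 change -1.44, or -0.79 with all-zero members at their bound, camera adjusted p = 0.725) had NODAL at -4.93 and LEFTY2 at 3.66, and 6 of 15 tested members rose, 5 fell and 4 did not pass (6 higher and 5 lower adjusted over the list alone). edgeR called 0 of the 3 measured skeletal muscle genes, and DESeq2 called 0, with 1 higher at an unadjusted p under 0.05 (median log2 change 0.55, camera adjusted p = 0.892).

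The comparison had 7144 genes higher and 6320 lower, of which 6184 and 5058 changed at least 2-fold. Of 27 lists in 8 comparisons, 99 of the 216 tests passed with a preset correlation, 61 upward and 38 downward, and 47 of them held with an estimated correlation.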

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

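The fits with GC content and length trends removed, and without 4 libraries (day 1 replicate 2, day 3 replicate 1, day 5 replicate 2 and day 10 replicate 1, those highest on a within-day axis), were tests chosen after results were seen. Other alternatives were set with the comparisons. Leaving out libraries aside, 142 counts of genes stayed within 1.5 times, 28 were larger and 6 smaller. Of the LPIN1 values, 81 kept their side of the threshold, 6 came past it and 1 fell short. No called gene list, LPIN1 value or other gene named here turned direction under any alternative run. Values not called crossed 0 for LPIN1 and POU5F1: day 28 against day 14 was 0.02 with no filter, against -0.05, and day 1 against day 0 was 0.01 with upper-quartile factors, against -0.06. POU5F1 at day 1 against day 0 was -0.13 with GC content and length trends removed, against 0.21.

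The gene lists called fell from 99 to 47 of 216 with an estimated correlation in place of the preset one. By fry 32 lists came past the threshold and 1 fell short, and with no filter 19 and 1. Lists that fell short and came past it were 9 and 5 with only the libraries of the 2 days, 9 and 8 without the 4 libraries, 8 and 8 with GC content and length trends removed, 4 and 3 with at least 50 counts, and 2 and 0 with the replicate block, RLE or upper-quartile factors. The cause was not tested.

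Without the 4 libraries the counts of genes higher and lower were 5169 and 5747 for day 1 against day 0, 3175 and 3154 for day 7 against day 5, 2919 and 2041 for day 14 against day 10, and 3591 and 2634 for day 28 against day 14. The lower count for day 5 against day 3 was 3214. With only the libraries of the 2 days they were 846 and 556 for day 5 against day 3, 528 and 227 for day 7 against day 5, 2384 and 2115 for day 10 against day 7, 957 and 904 for day 14 against day 10, and 3216 and 3058 for day 28 against day 14. With GC content and length trends removed they were 2228 and 2445 for day 7 against day 5, 2019 and 1611 for day 10 against day 7, 856 and 1049 for day 14 against day 10, and 3067 and 3102 for day 28 against day 14, and 2557 lower for day 5 against day 3. Library totals alone gave 707 lower for day 7 against day 5, 597 higher and 1270 lower for day 10 against day 7, and 2660 lower for day 28 against day 14. DESeq2 gave 585 higher and 729 lower for day 14 against day 10. The cause of the other shifts was not tested.

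Library totals alone moved the median of all genes by 0.23 (day 3 against day 1), 0.15 (day 7 against day 5), -0.18 (day 10 against day 7), -0.21 (day 28 against day 14) and -0.12 (day 28 against day 0) on the log2 scale. Upper-quartile factors moved it by -0.12 for day 28 against day 14.

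LPIN1 fell short for day 5 against day 3 with only the 2 days (-1.46). It passed for day 7 against day 5 with GC and length trends removed (0.63) and without the 4 libraries (0.92). For day 10 against day 7 it passed with DESeq2 (0.84), with only the 2 days (0.84) and with the trends removed (0.78). Without the 4 libraries, with day 10 replicate 2 alone, day 14 against day 10 was 0.85. The cause was not tested.

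Leaving out each library in turn, the counts higher ran from 1992 to 4357 and lower from 1913 to 4040 (day 1 against day 0), 2882 to 4563 and 2823 to 3949 (day 3 against day 1), 1716 to 3307 and 1162 to 4579 (day 5 against day 3), 879 to 2227 and 432 to 1808 (day 7 against day 5), 202 to 479 and 90 to 559 (day 10 against day 7), 65 to 254 and 121 to 524 (day 14 against day 10), 1315 to 1547 and 972 to 1262 (day 28 against day 14), and 6356 to 6849 and 5312 to 5679 (day 28 against day 0). LPIN1 ran from -0.17 to 0.06, 1.74 to 2.15, -1.83 to -1.12, 0.31 to 1.00, 0.52 to 1.06, 0.23 to 0.78, -0.08 to 0.03 and 2.36 to 2.51 in the same order. Without a day 10 library, the lone one is assumed to vary like the other days.

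Replicate numbers did not pair the libraries: 13 of 77 same-number pairs had deviations correlated above 0.1 (r from -0.46 to 0.65), and 7 of 23 libraries matched their own number best. With the number as a block the genes called were 7090, 8176, 3556, 2140, 1282, 906, 3431 and 13378. The mean totals and the simulated check are described above.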

Other observations

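The tests of a single library and of overlapping reads for LPIN1, of progress along the course, of the cardiomyocyte share and of S phase were chosen after the results were seen. So were the genes in the next paragraph.

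Some genes peaked within the course or dipped at day 14. CGA went from 0.333 CPM at day 5 to 122 at day 7, 23.3 at day 10 and 1.06 at day 14, with log2 changes of 8.31 to day 7 and -4.43 from day 10 to day 14. ACTA1, skeletal alpha actin, was at 218 CPM at day 7, 242 at day 10, 36.7 at day 14 and 905 at day 28, with log2 changes of -2.72 and then 4.62. NPPA took the same path, -2.48 and then 2.28.

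LPIN1 stood higher at day 3 than at days 1 and 5. Over fits without each library in turn, its smallest difference from either day was 1.12, which argues against 1 library carrying it. Among the 200 genes nearest in GC content, length and level, LPIN1 lay at percentile 99 (1.42 against a median of -0.36 and a 95th percentile of 0.53), which argues against such a trend. Genes overlapping LPIN1 held 0.936% of its count at day 3 (28 of 2993), too few to make the peak. No biological explanation was tested.

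Libraries of several days deviated from their day's mean along 1 shared axis, with 35.6% of the within-day variance; day 5 replicates 2 and 3 lay farthest out, at opposite ends (0.60 and -0.56), then day 3 replicate 1 (0.32) and day 1 replicate 2 (0.26). Thinning every library to 4330334 counts left 33.35%, which argues against depth as such, though the score went with the log2 total within days (Pearson r = 0.84, adjusted p = 0.0141 by 100000 permutations, 23 libraries; 0.66 without those 2 of day 5). Removing GC and length trends left 19.485%, between the bounds set, so trend and axis cannot be told apart. The trends were largest in the libraries named above: R-squared 54.1%, 41.3%, 46.7% and 37.7% in that order, against a median of 9.56%. Progress along the course stays open: r with the deviation towards the next day was -0.12 over 17 libraries (permutation p = 0.738), but 0.48 without the 2 of day 5. Library construction was not tested.

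The cell cycle list was called higher at day 28 than at day 14 (median 0.44, 7 of 35 members called), a call lost with an estimated correlation (adjusted p = 0.486), with only the libraries of the 2 days, without day 14 replicate 1 (0.0828) or without day 28 replicate 3 (0.144). A smaller cardiomyocyte share stays open, as other cell types need not change alike. The fibroblast list rose (median 2.29, 13 of 14 members called higher), and the sarcomere list was called higher too. The endoderm and liver list fell (-2.12, 10 of 14 called lower), though it was not called with an estimated correlation (adjusted p = 0.129). The median with GC and length trends removed was 0.42 (adjusted p = 0.00135), which argues against such a trend. More cells in S phase could raise the list. The histone list had a median of -0.37, but camera did not set it apart from other genes (adjusted p = 0.0848), so this stays open. Growth of the stromal cells whose markers rose was not tested.

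Other splits of the 6 libraries into 3 and 3 were fitted for 6 comparisons. With 10 splits no share can be under 0.05. The real split called 7081 genes for day 1 against day 0 and 8276 for day 3 against day 1. It called 2301 for day 7 against day 5, 3501 for day 28 against day 14 and 13464 for day 28 against day 0. In each, the highest other split called 0 by edgeR. For day 5 against day 3, 3 of 10 splits called as many: the real one (3698) and others with 6275 and 5404. Those put day 3 replicate 1 with day 5 replicate 2, opposite day 5 replicate 3, and point to a structure of the samples.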
